A study of Arabidopsis thaliana with 30 samples.

How the data were processed

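ATAC-seq peak lists of 30 Arabidopsis libraries were analysed, 2 per group in 15 groups: Col-0 root, stem and shoot, and shoots of 12 mutant genotypes. Plants were 2 weeks old, and 4 weeks old for stem. Per the labels' protocols, nuclei were tagmented with Tn5, libraries were amplified by PCR and sequenced on a NovaSeq X Plus. Per the submitters' processing notes, reads were checked with FastQC, aligned to TAIR10 with BWA, handled with SAMtools and GATK, and peaks were called with MACS2, without versions. Reads were not analysed here, so alignment rate, duplicates and fragment lengths are not known.

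The deposited lists hold 1 peak per line. The score deposited by the authors is the whole part of 10 times the −log10 q value, to within 1, in 100% of lines of each list. The fold deposited by the authors is the ratio of the fragment pileup at the summit to the local background, as MACS2 writes it, and is not on a log scale. The −log10 p and −log10 q values were deposited by the authors as MACS2 made them, and the smallest −log10 q in any list, 2.00, shows the calling threshold. Start, end and summit offset are coordinates deposited by the authors on TAIR10. Position of elements against genes was checked in 59 bins of 2 Mb: in all of them the share of elements outside genes was highest at a shift between −200 and 200 bp, and 68.1% of elements lay outside genes there against 37.5% after shifting.

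Depth is not stated in the lists. The Poisson model behind the fold and the −log10 p value was inverted to give the background level in fragments at each peak, and the median over peaks at the lowest such level of a library, its floor, stands for depth. As a pileup of fragments it can also differ with fragment length, which is not known. The floors below are given by replicate. The floor was 11.8 and 10.6 in root, 8.71 and 12.0 in stem, and in shoot 6.60 and 8.48 in Col-0, 7.21 and 5.17 in ros1-4, 9.42 and 14.8 in rdd-2, 9.05 and 8.64 in drdd, 18.6 and 13.3 in met1-9. It was 8.30 and 6.67 in nrpd1-3, 7.73 and 8.20 in nrpd1-3 ros1-4, 25.9 and 32.5 in gcn5, 16.2 and 25.2 in gcn5 ros1-4, 7.03 and 6.68 in hda6, 9.12 and 12.9 in hda6 ros1-4, 9.03 and 5.19 in sdg2-4, and 8.06 and 7.42 in sdg2-4 ros1-4. The lowest fold called at background runs from 2.42 in sdg2-4 replicate 2 to 1.61 in gcn5 replicate 2, so weaker peaks enter the deeper lists.

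Samples were grouped by the tissue and genotype of their labels. For met1-9 the labels say shoot while the peak names say leaf and carry another series prefix, so the organ may differ from that of its Col-0 reference. Numbers in the peak names, taken as a possible order of preparation, run from 26 to 43 for Col-0, ros1-4, rdd-2, drdd and the nrpd1-3 pair, from 50 to 53 for stem and root, from 54 to 58 for hda6 and sdg2-4, from 62 to 65 for their ros1-4 doubles and from 76 to 79 for the gcn5 pair. Batches are not stated, and hda6 and sdg2-4 lie in another range than their doubles. Root, stem, hda6, sdg2-4, gcn5 and met1-9 also lie in another range than Col-0 shoot. Their comparisons with Col-0 shoot therefore cross ranges, and a difference of preparation cannot be told apart from tissue or genotype there. Replicate numbers do not pair libraries: over 105 pairs of groups the correlation of replicate differences ran from −0.154 to 0.165. The labels link no library of 1 group to a library of another, so the replicate number as a block stands only among the alternatives. Peak names of both stem libraries hold words for merged or added data, so their depth may come from several runs.

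Summits of all lists, ranked by their within-list percentile of −log10 q, set windows reaching 150 bp to either side, and lower summits whose window overlapped a higher one were dropped. This gave 48484 windows, of which the 42611 with a peak in both libraries of at least 1 group are the elements. A peak is present when it overlaps the element by at least 1 bp, so a wide peak can cover several elements. The reference gene table gives neither strand nor transposable elements. A gene-end window therefore runs from 1000 bp outside to 200 bp inside either end of a protein-coding gene. Pseudogenes stand as a class of their own, and gene-poor windows are those of 100 kb with less than 25% of protein-coding gene sequence, a limit chosen after the files were seen. No genome sequence was at hand, so motifs were left out. Elements were named by the nearest protein-coding gene within 2000 bp. Reads at 3.2 to 3.5 Mb of chromosome 2, a mitochondrial insertion, and near 14.2 Mb of chromosome 3 can come from near-identical copies.

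In 15 comparisons of 2 groups, lost and gained elements were counted beside the counts from the 2 other pairings of the same libraries. Gene lists of 239 entries in 10 groups, with EPF2 in 2 of them, were fixed before the data were examined: DNA methylation machinery, loci controlled by DNA methylation, photosynthesis, root development and uptake, secondary wall and vascular tissue, floral transition, leaf and stomatal development, immune response, heat and drought response, and housekeeping. Each list was compared with all other genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 60 tests for tissues and 240 for genotypes. A gene was measured when an element in its window carried a peak in both libraries of either group. The same test set the classes of changed elements against the other elements that could have been lost or gained, adjusted over the 4 classes in all comparisons and apart from them over the gene-poor tests; 112 of 150 tests passed 0.05. Elements are not independent samples, so these p values describe the lists and not the variation between plants.

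ROS1 and ros1-4 were compared in 5 backgrounds, 10 libraries against 10. Two-sided exact permutation tests exchanged libraries only within a background, in 7776 arrangements, on peaks per list and shares of classes (adjusted over 6 values) and on each element that could reach a p under 0.05. The limma model on presence of a peak, with background as a factor, was the other tool. Tested on simulated data with 100 elements lost completely, the exact test with adjustment found 62%, limma 99% and the comparison of 2 with 2 libraries 90%. With partial loss these shares were 2%, 56% and 47%. Of 169 simulated limma calls 14 were unchanged elements, and of 64 exact calls 0. The simulation drew each library independently of its replicate and took changed elements from those present in most libraries, so error rates in the real lists can differ. Elements lost or gained in ros1-4 against Col-0 were tested in the other 4 backgrounds on each library's share with a peak, minus that of the other elements. Overlaps of sets that share the Col-0 libraries stand beside 200 simulations without change.

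Named genes follow a rule set in advance. Per comparison these are listed genes with a changed element, up to 12 each way by strength, and the 6 strongest lost and gained elements, where strength is the lower of the 2 percentile ranks of −log10 q. For the 10 against 10 comparison they are the 10 smallest p each way, and the genes removed by the mutations are given in every group. Alternatives were a stricter threshold of −log10 q of at least 5, an overlap of at least 151 bp, lists of equal length, a wider gene window, a replicate block, rdd-2 and drdd added to ros1-4, stratification by peak height, and leaving out each library in turn. After the results were seen, a detection limit was added: both folds at least 2 times the lowest fold called at background in the libraries without a peak.

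Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with limma 3.58.1 were used.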

Results

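Accessible chromatin was profiled by ATAC-seq, in which the Tn5 transposase inserts adapters into open DNA, in nuclei of Arabidopsis thaliana. The 30 libraries fell into 15 groups of 2. Col-0 wild type was sampled as 2-week root, 2-week shoot and 4-week stem, and 12 mutant genotypes were sampled as 2-week shoot. The mutants lacked ROS1, a DNA demethylase (ros1-4), ROS1 with DML2 and DML3 (rdd-2), or all of these with DME (drdd). Others lacked MET1, the maintenance methyltransferase of CG sites (met1-9), NRPD1, the large subunit of RNA polymerase IV in RNA-directed DNA methylation (nrpd1-3), the histone acetyltransferase GCN5 (gcn5), the histone deacetylase HDA6 (hda6) or the histone H3K4 methyltransferase SDG2 (sdg2-4). The last 4 were also combined with ros1-4.

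The peak lists held 734458 peaks in all, from 17315 in Col-0 stem replicate 1 to 38392 in met1-9 replicate 1. The lists give no read counts. The background level of a library, as read back from the deposited folds and −log10 p values, ran from 5.17 fragments in ros1-4 replicate 2 to 32.5 fragments in gcn5 replicate 2, so depth differed widely between groups. Peaks were gathered into 42611 elements of equal width, of which 12881 carried a peak in all 30 libraries. Of the elements, 71.7% lay in a gene-end window, 8.04% elsewhere in a gene body, 1.33% in a pseudogene and 19.0% in none of these. Libraries of 1 group shared from 74.3% (hda6) to 93.0% (gcn5) of the elements that either carried. An element is called lost when both reference libraries and neither test library carried a peak, and gained in the reverse case. With 2 libraries against 2 the smallest p of an exact test is 0.333, so no element was tested in these comparisons, and the count of the real pairing stands beside the highest of the 2 other pairings of the same 4 libraries.

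**Figure D1:**
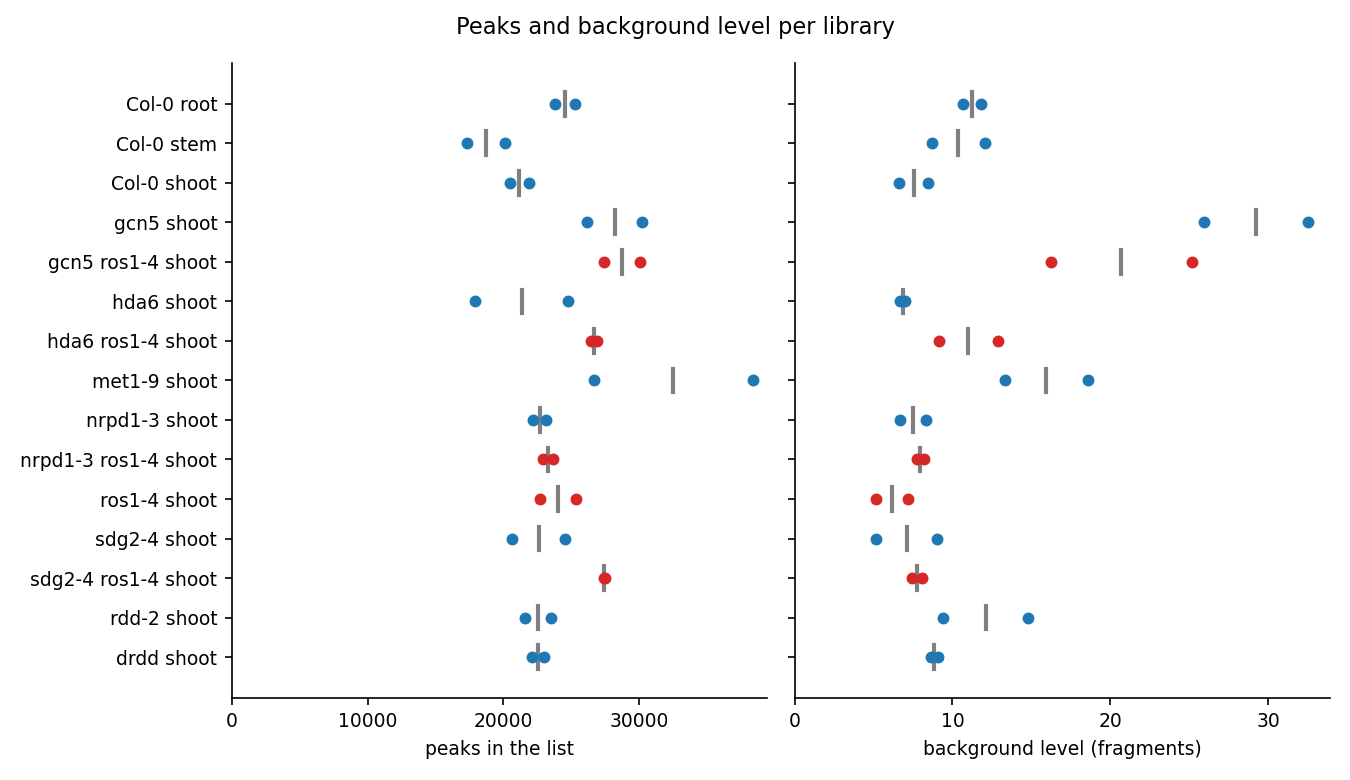
Peaks per list (left) and background level in fragments (right) of each of the 30 libraries by group; points are libraries, grey bars are group means, and red marks genotypes with ros1-4. The gcn5 libraries have the highest background levels, 25.9 and 32.5 fragments, and the met1-9 libraries are the farthest apart in peaks, 26663 and 38392.

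Root was set against shoot to find where open chromatin differs between organs. Genes of photosynthesis lost elements in root: 12 of 32 measured list genes, among them LHCB2.1, LHCB1.3 and LHCB2.2, which encode light-harvesting proteins, and GLK1, a transcription factor of chloroplast development. The LHCB2.1 element (chromosome 2, 1824341 to 1824641) had folds over background of 12.1 and 13.2 in the shoot libraries and was listed in neither root library. Root development genes gained elements, 13 of 24, including the root hair regulators RHD6 and RSL4, the auxin carrier gene PIN2 and the phosphate transporter gene PHT1;1. The RHD6 element (chromosome 1, 24797460 to 24797760) had folds of 6.20 and 6.29 in root and was listed in no other library. Secondary wall and vascular genes also gained elements, 14 of 25, among them KNAT1 and MYB63. These lists differed from all other genes by Fisher's exact test, with adjusted p = 0.000946, 0.00507 and 0.00249, where 9.27% of other genes lost and 21.4% gained an element. Immune genes lost elements in 6 of 20 cases, at an adjusted p of 0.0599 over all tests and 0.0399 over this comparison alone by Fisher's exact test.

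The strongest lost elements in root beside LHCB2.1 lay at RPP13, a disease resistance gene, at AT5G09210 and at MEE14. The strongest gained ones lay at AGO6, an Argonaute of RNA-directed DNA methylation (chromosome 2, 13970945 to 13971245, folds of 8.98 and 9.90), at AT3G22436 and at AT5G56220. In all, 2304 elements were lost and 5629 gained in root, while no other pairing of the 4 libraries gave more than 439. Root against shoot gave 3196 lost and 3900 gained elements with lists of equal length, and 722 and 760 with folds at least 2 times the detection limit. With lists of equal length the secondary wall genes no longer passed, 7 of 19 at adjusted p = 0.162 by Fisher's exact test, while floral genes passed among the lost, 5 of 8 at adjusted p = 0.0205.

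Stem was set against shoot with the same question. The stem plants were older than the shoot plants, so a difference of organ cannot be told apart from one of age here. Secondary wall and vascular genes gained elements in stem, 8 of 21 against 8.25% of other genes (Fisher's exact test, adjusted p = 0.00249). They were IRX10, which makes the xylan backbone, the lignin regulators MYB58, MYB63 and MYB103, the wall regulator MYB83, KNAT1, KNAT7 and the cambium regulator WOX4. The MYB58 element (chromosome 1, 5631596 to 5631896) had folds of 3.63 and 3.27 in stem and was listed in no shoot library. Photosynthesis genes lost elements in 9 of 32 cases, at an unadjusted p of 0.0319 and an adjusted p of 0.191 by Fisher's exact test. The strongest gained elements lay at TCX2, AT1G01570 and ATAUX2-11, and the strongest lost ones outside repeated sequence at PHI-1, MEE14 and AT1G72130.

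Stem lost 2599 and gained 1977 elements against shoot, and no other pairing gave more than 706. Stem against shoot gave 1735 lost and 2859 gained elements with lists of equal length, which turns the larger side, and 537 and 182 at the detection limit. Peak names of the stem lists hold words for merged or added data, so these lists may pool several runs. Without Col-0 stem replicate 2 the total was 6959, and without replicate 1 there were 2944 lost and 3570 gained, which turns the larger side. The 3 strongest lost elements, at AT2G07728, AT2G07698 and AT3G41762, lie where the reference holds near-identical copies of other sequence, so reads may be shared and they are uncertain.

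Root against stem placed these organs beside each other. The stem plants were also older than the root plants, so organ and age cannot be told apart in this comparison either. Root development genes gained elements in root, 15 of 23 against 24.4% of other genes (Fisher's exact test, adjusted p = 0.0012), including FIT and FRO2 of iron uptake, HAK5 of potassium uptake, PLT2, SCR and PIN2. Photosynthesis genes lost elements in root, 8 of 30 against 6.48% (adjusted p = 0.00507 by the same exact test), with LHCB2.1, LHCB1.3, LHCA3 and RBCS3B among them. NRPD1 (chromosome 1, 23354091 to 23354391) gained its element, with folds of 5.70 and 4.66 in root and no peak in stem. AGO6 and AT5G11710 were among the strongest gained, and ROPGEF4 and AOC2, a jasmonate synthesis gene, among the strongest lost.

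Root lost 1670 and gained 5631 elements against stem, with at most 398 in another pairing. Root against stem gave 3222 lost and 2736 gained elements with lists of equal length, which turns the larger side, and 343 and 934 at the detection limit. With a wider gene window the root development genes no longer passed, 16 of 31 at adjusted p = 0.158 by Fisher's exact test.

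**Figure D2:**
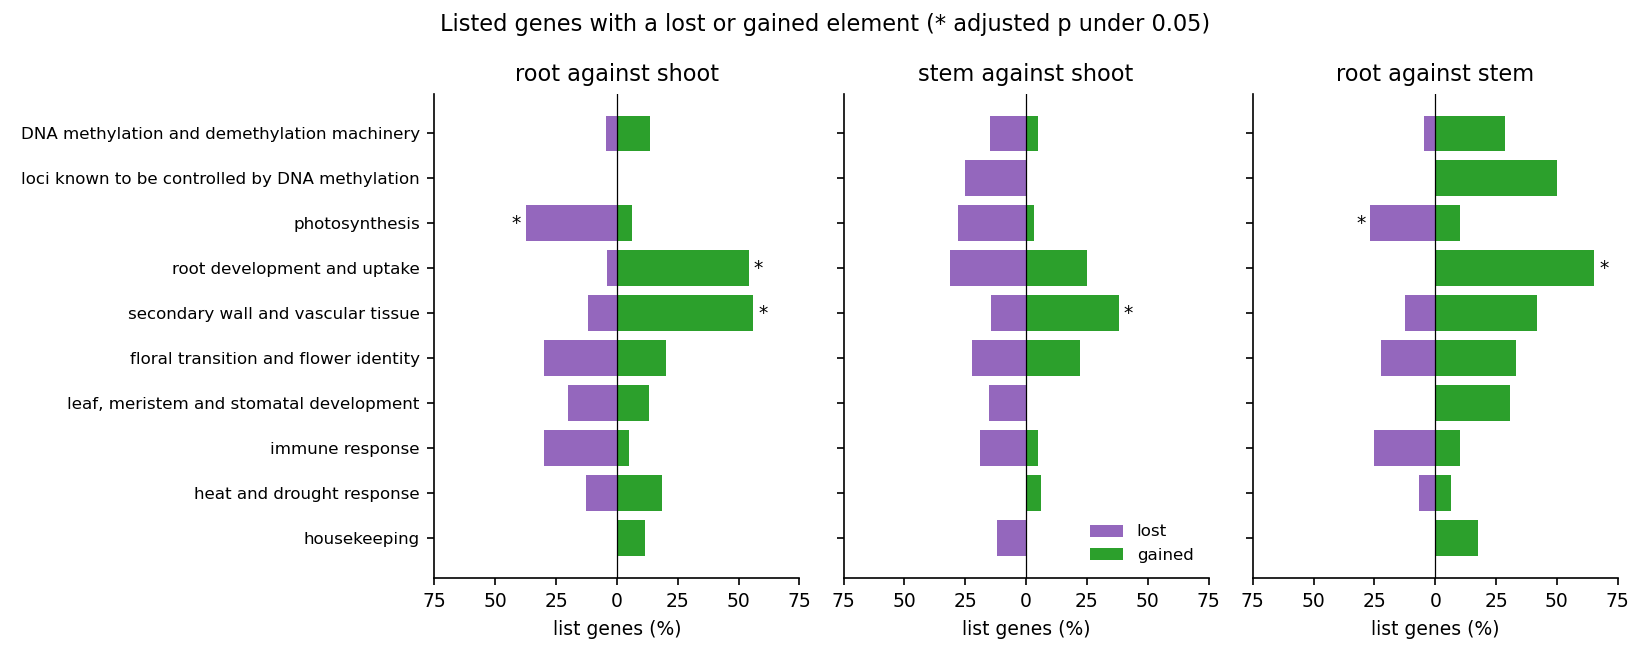
Share of measured genes of each list (%) with a lost (purple) or a gained element (green) in the 3 organ comparisons, a panel each; stars mark lists with an adjusted p under 0.05 by Fisher's exact test. Photosynthesis genes stand out among the lost in root, 12 of 32 against shoot, and root development genes among the gained, 13 of 24.

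The ros1-4 mutant was set against Col-0 shoot to find elements that depend on the demethylase. RMG1, an immune receptor gene under the control of DNA methylation, lost an element (chromosome 4, 6810878 to 6811178), which had folds of 4.87 and 5.49 in Col-0 and was listed in neither ros1-4 library. XCP2, a xylem protease gene, SPL3, LHCB5, LHCB2.2 and PR1, a marker of salicylic acid signalling, also had a lost element. The strongest lost elements lay at PHI-1, AT2G24330, STL2P, RLP9, AT5G57565 and AT3G25910. The STL2P element (chromosome 2, 215275 to 215575) had folds of 10.5 and 10.8 in Col-0, and the RLP9 element (chromosome 1, 21540448 to 21540748) had folds of 8.42 and 8.59. Gained elements included those at CAL and LFY, regulators of flower identity, and the strongest outside repeated sequence lay at ATCSLA09 and AT3G21100. By Fisher's exact test 0 of 240 gene list tests passed the adjusted threshold in the 12 genotype comparisons, over all of them or over each comparison alone, and 15 had an unadjusted p under 0.05; no other tool was used on the lists.

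Elements lost in ros1-4 lay away from genes more often than the other elements of Col-0. Of the 687 lost elements, 9.02% lay in gene-poor windows against 2.12% of the others (Fisher's exact test, adjusted p = 1.05e-19), and 62.7% in gene-end windows against 78.7% (adjusted p = 2.88e-20). A lower gene-end share of lost elements was seen in all 15 comparisons, where it ran from 52% in gcn5 to 71.3% in nrpd1-3. A higher gene-poor share was also seen among elements lost in some mutants with ROS1. It was 14.7% against 2.29% in gcn5, 6.71% against 2.27% in met1-9 and 3.90% against 2.29% in nrpd1-3. The share was lower in hda6, 0.833% against 2.39%, and in sdg2-4, 1.05% against 2.37%. There were 1350 gained elements, and another pairing gave up to 652 changed elements. The ros1-4 comparison gave 1243 lost and 704 gained elements with lists of equal length, which turns the larger side, and 121 and 126 at the detection limit. Without ros1-4 replicate 1, ros1-4 replicate 2, Col-0 shoot replicate 1 or Col-0 shoot replicate 2 the total was 3997, 3162, 3539 or 4195, since 1 library then stands for its group.

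The rdd-2 and drdd mutants were set against Col-0 to ask what the loss of further demethylases adds. Both lost the STL2P element, the MEE14 element (chromosome 2, 6922377 to 6922677) and an element at CRK40, a receptor-like kinase gene (chromosome 4, 2288848 to 2289148), which had folds of 12.7 and 11.1 in Col-0. XCP2 lost its element in both, as in ros1-4, while the RMG1 element was lost in drdd and present in both rdd-2 libraries. Another RMG1 element (chromosome 4, 6817044 to 6817344) was gained in rdd-2, with folds of 6.24 and 5.70, and in drdd, with 6.57 and 5.19, within a wide peak that also covers elements open in Col-0. In drdd the wall genes IRX8 and NST1 also had a lost element, so that 3 of 17 measured secondary wall genes did, at an unadjusted p of 0.00713 and an adjusted p of 0.571 by Fisher's exact test. Elements at AT5G32440 and at ATAUX2-11, an auxin response gene, were gained in both, with AT5G32440 (chromosome 5, 12078710 to 12079010) at folds of 15.5 and 14.8 in rdd-2 and 17.7 and 18.0 in drdd.

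In rdd-2, 479 elements were lost and 1317 gained (at most 843 in another pairing), and in drdd 585 were lost and 1358 gained (at most 622). Gene-poor windows held 7.31% of the lost elements of rdd-2 and 9.06% of those of drdd, against 2.22% and 2.15% of the others (Fisher's exact test, adjusted p = 4.69e-09 and 4.87e-17). The rdd-2 comparison gave 724 lost and 942 gained elements with lists of equal length and the drdd comparison 751 and 893, while at the detection limit the larger side turns, with 104 and 71 in rdd-2 and 227 and 121 in drdd. Without rdd-2 replicate 1 or 2 the rdd-2 total was 3647 or 3018, and without Col-0 shoot replicate 1 or 2 it was 3210 or 3873. Without drdd replicate 1 or 2 the drdd total was 3070 or 3363, and without Col-0 shoot replicate 1 or 2 it was 3419 or 4206.

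The 3 demethylase genotypes were then compared with each other through the elements they lost. STL2P, RLP9, AT5G04020, AT2G13985, AT2G33830, AT3G15605 and DOGL4 lay at elements lost in ros1-4, rdd-2 and drdd alike, and 166 elements were lost in all 3. Between ros1-4 and rdd-2, 255 lost elements were shared, between ros1-4 and drdd 277, and between rdd-2 and drdd 232. All 3 comparisons use the same Col-0 libraries, so elements that recur, as those at AT5G32440, MEE14 and RLP9 do in further mutants, cannot be told from a difference of those libraries. Groups simulated without any change shared 51.9 lost elements on average, though they had fewer lost elements (267 on average against 479 to 687), while independent sets would share 15.1, 18.4 and 12.8. Gained elements were shared in 500, 481 and 580 cases, against 577.81 in the simulated groups, which had more gained elements (1724 on average), and 112, 115 and 112 for independent sets. Without Col-0 shoot replicate 1 or 2, 397 or 280 elements were lost in all 3.

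The met1-9 mutant was set against Col-0 to find elements held closed by CG methylation. SDC (chromosome 2, 7681563 to 7681863) and FWA (chromosome 4, 13038136 to 13038436), genes kept silent in vegetative tissue by DNA methylation, carried a peak in both met1-9 libraries and in no other library. Folds were 8.95 and 8.44 at SDC, and −log10 q was 253 and 67.6 at FWA. With QQS and RMG1, whose element (chromosome 4, 6817044 to 6817344) lies in replicate 2 within a peak that also covers a neighbouring element open in Col-0, 4 of 7 measured loci known to be controlled by DNA methylation gained an element, at an unadjusted p of 0.0393 and an adjusted p of 0.76 by Fisher's exact test. Immune genes gained elements in 9 of 22 cases, including PR1, PR2, RPP4 and CBP60G, at an unadjusted p of 0.0327 and an adjusted p of 0.713 by the same exact test. In both tests 21.0% of the other genes gained an element in met1-9. The 6 strongest gained elements lay far from any protein-coding gene, and each was listed in the met1-9 libraries alone. The strongest of them (chromosome 3, 12209745 to 12210045) had folds of 34.8 and 39.3.

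Of the 6435 elements gained in met1-9, 24.6% lay in gene-poor windows, against 3.55% of the other elements absent from Col-0, and 5.63% lay in pseudogenes against 0.739% (Fisher's exact test, adjusted p = 2.69e-77 for pseudogenes and smaller for gene-poor windows). Elements were defined from all libraries, met1-9 among them, so the sites it alone opens count in the first share only. Only 298 elements were lost, among them elements at PIP1A, an aquaporin gene, MYB6 and LDL2, a histone demethylase gene, and no other pairing gave more than 909. The met1-9 comparison gave 2524 lost and 2457 gained elements with lists of equal length, which turns the larger side, and 52 and 2021 at the detection limit. Without met1-9 replicate 2 the total was 11004. The gene-poor share of gained elements was 41.02% at the detection limit, 16.2% without met1-9 replicate 2 and 24.5% without replicate 1, which has the longer list.

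**Figure D3:**
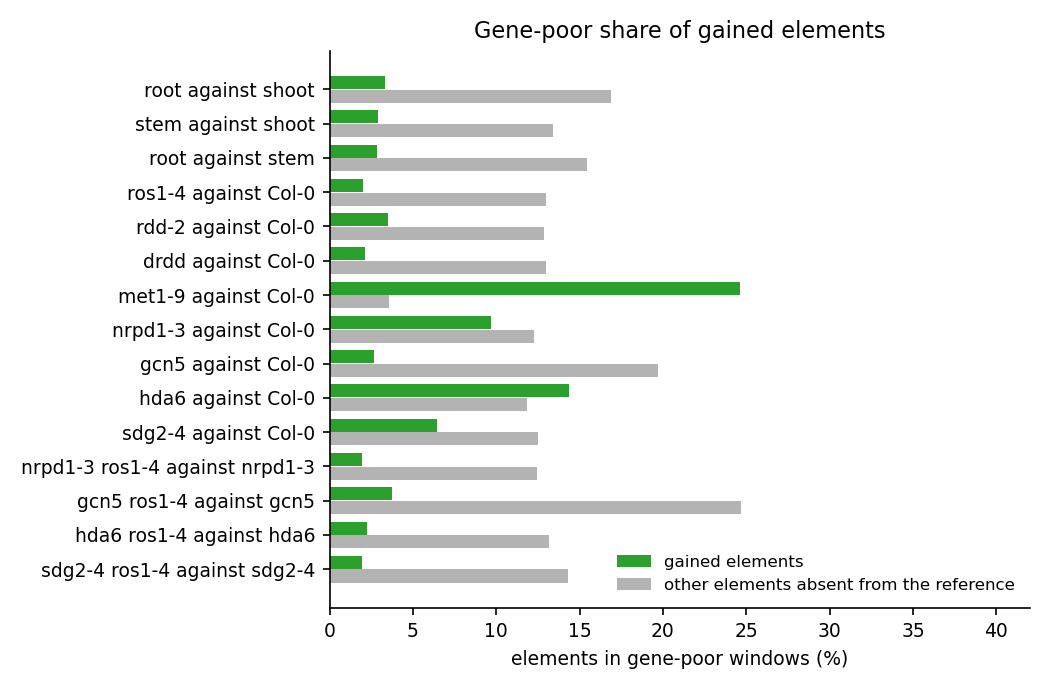
Share of elements in gene-poor windows (%) among the gained elements of each of the 15 comparisons (green) and among the other elements absent from the reference libraries (grey). The gained share in met1-9, 24.6%, is the highest of the 15, followed by hda6 with 14.4%. In comparisons other than that of met1-9 the grey bars can hold elements gained in met1-9.

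The nrpd1-3 mutant was set against Col-0 to find elements that depend on RNA polymerase IV. HDG9, a homeobox gene on the list of loci controlled by DNA methylation (chromosome 5, 5702765 to 5703065), gained an element with folds of 6.13 and 6.13. Strong gained elements lay at AT2G06555 and at CHL, which encodes a chloroplast lipocalin, and in chromosome 3 sequence with no gene within 2000 bp (14859747 to 14860047, folds of 15.2 and 14.2). Lost elements lay at PUB39, RLP9, AT2G35880 and PHS1, and at the leaf polarity genes FIL and AS2. Of immune genes, PR1, ICS1 and WRKY33 had a lost element, 3 of 21 at an unadjusted p of 0.0303 and an adjusted p of 0.713 by Fisher's exact test. The nrpd1-3 libraries lost 616 and gained 1241 elements, with at most 722 in another pairing. The nrpd1-3 comparison gave 931 lost and 882 gained elements with lists of equal length, which turns the larger side, and 52 and 230 at the detection limit. Without nrpd1-3 replicate 1 or 2 the total was 3471 or 3234, and without Col-0 shoot replicate 1 or 2 it was 3439 or 3780.

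The gcn5 mutant was set against Col-0 to find elements that depend on this acetyltransferase. Root development genes gained elements in 14 of 23 cases, including the Casparian strip genes CASP1, CASP2 and CASP4, RSL4 and TMO5, at an unadjusted p of 0.00564 and an adjusted p of 0.571 by Fisher's exact test. Of the other genes, 31.9% gained an element in gcn5. The strongest gained elements lay at ASL15, at the cellulose synthase gene CESA2 (chromosome 4, 18301668 to 18301968, folds of 13.6 and 13.6), at AT5G32440 and at BG1. Lost elements were few, and the strongest lay at DOGL4 (chromosome 4, 10266459 to 10266759), at AT2G33175 and at JAZ5, a repressor gene of jasmonate responses. In gcn5, 75 elements were lost and 7124 gained, and no other pairing gave more than 179. The background level was 29.2 ± 4.66 fragments in gcn5 and 7.54 ± 1.33 in Col-0 (SD, n = 2 each). The gcn5 comparison gave 676 lost and 2271 gained elements with lists of equal length and 22 and 730 at the detection limit.

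The hda6 mutant was set against Col-0 to find elements held closed by this deacetylase. QQS, an orphan gene of starch metabolism whose silencing depends on DNA methylation (chromosome 3, 12348790 to 12349090), gained an element with folds of 8.45 and 5.86, and RMG1 gained one (chromosome 4, 6817044 to 6817344) with folds of 6.48 and 6.12, within a peak that also covers a neighbouring element open in Col-0 (6817417 to 6817717). The same RMG1 element was gained in rdd-2, drdd and met1-9 as well, and in gcn5 with folds of 5.23 and 6.20. In hda6, QQS and RMG1 were 2 of 5 measured loci of their list, at an unadjusted p of 0.0322 and an adjusted p of 0.713 by Fisher's exact test. The 2 strongest gained elements lay in gene-free sequence of chromosomes 4 (2170688 to 2170988) and 5 (9561597 to 9561897). Lost elements lay at AT3G10330, MEE14, RLP9, Tic32-IVa and PI, a flower identity gene. In hda6, 720 elements were lost and 1385 gained, and another pairing gave up to 1149. Gene-poor windows held 14.4% of the gained elements against 11.9% of the others (Fisher's exact test, adjusted p = 0.00889). These others hold elements gained in met1-9. Of the elements absent from Col-0 and not gained in met1-9, 3.55% lay in gene-poor windows. The hda6 comparison gave 756 lost and 1239 gained elements with lists of equal length and 39 and 291 at the detection limit. Without hda6 replicate 1 or 2 the total was 4994, with 3061 lost and 1933 gained, which turns the larger side, or 4730, and without Col-0 shoot replicate 1 or 2 it was 3506 or 3707.

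The sdg2-4 mutant was set against Col-0 to find elements that depend on this methyltransferase. Lost elements lay at AT5G06970, AT3G10330, PUB39, MEE14, RLP9 and at SCAMP5 beside PRK, a Calvin cycle gene (chromosome 1, 11531190 to 11531490, folds of 8.85 and 10.2 in Col-0). The root genes LBD16, PHT1;4 and WOX5 had a lost element, 3 of 17 at an unadjusted p of 0.0195 and an adjusted p of 0.713 by Fisher's exact test, and so did the stomatal regulator gene SPCH. Gained elements lay at AT5G32440, AT5G53050, AT1G01570 and HSP17.4, a heat shock gene. In sdg2-4, 666 elements were lost and 1091 gained, and another pairing gave up to 1121, so the real pairing exceeded it by less than 2 times. The sdg2-4 comparison gave 1097 lost and 810 gained elements with lists of equal length, which turns the larger side, and 64 and 86 at the detection limit. Without sdg2-4 replicate 1 or 2 the total was 3814, with 2396 lost and 1418 gained, or 3973, and without Col-0 shoot replicate 1 or 2 it was 3183 or 3524.

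Each of 4 double mutants was set against its single mutant to see what the loss of ROS1 does there. In nrpd1-3, adding ros1-4 lost the element at EPF2, a signal peptide gene that limits stomatal divisions (chromosome 1, 12472064 to 12472364, folds of 2.50 and 2.52 in nrpd1-3), as well as elements at SPCH and AN3. These were 3 of 12 leaf and stomatal genes, at an unadjusted p of 0.00592 and an adjusted p of 0.571 by Fisher's exact test. PHI-1, AT4G17070, AIB and AT3G15605 lay at the strongest lost elements, and BG1, LHCB1.3 and SRF3 at the strongest gained ones. There were 714 lost and 1043 gained elements, with at most 589 in another pairing. The nrpd1-3 ros1-4 comparison gave 819 lost and 853 gained elements with lists of equal length and 84 and 112 at the detection limit. Without nrpd1-3 ros1-4 replicate 1 or 2 the total was 3137 or 2966, and without nrpd1-3 replicate 1 or 2 it was 3365 or 3406.

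In gcn5, adding ros1-4 lost the RMG1 and XCP2 elements, as in ros1-4 alone, with RMG1 at folds of 10.1 and 7.43 in gcn5. The strongest lost elements lay at ASL15, at TPR2, a corepressor gene, at RPS6, a disease resistance gene, at iPGAM2 and at PHI-1. Gained elements lay at AT4G36000, AT4G10695, RAN-1, JAZ5 and the cellulose synthase gene CESA6. In gcn5 against Col-0, ASL15 had a gained and JAZ5 a lost element. There were 1633 lost and 374 gained elements, with at most 461 in another pairing. The background level was 20.7 ± 6.35 fragments with ros1-4 and 29.2 ± 4.66 without (SD, n = 2 each). The gcn5 ros1-4 comparison gave 1519 lost and 314 gained elements with lists of equal length and 359 and 35 at the detection limit. Without gcn5 ros1-4 replicate 2 or gcn5 replicate 1 the total was 3324 or 3353.

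In hda6, adding ros1-4 lost the STL2P element, with folds of 14.8 and 10.9 in hda6, the DOGL4 element and the iPGAM2 element, and elements in gene-free sequence of chromosomes 3 (15025593 to 15025893), 2 (9121910 to 9122210) and 4 (2169910 to 2170210). Of the 270 lost elements, 20.4% lay in gene-poor windows against 3.16% of the others (Fisher's exact test, adjusted p = 4.59e-27). Gained elements, 2466 in all, lay at AT3G10330, MEE14, AT5G53050 and at APT1 beside IRX10, and no other pairing gave more than 456. AT3G10330 and MEE14 also had an element lost in hda6 against Col-0. The double lies in another number range than hda6, so preparation cannot be told apart from ros1-4 here. The hda6 ros1-4 comparison gave 723 lost and 666 gained elements with lists of equal length, which turns the larger side, and 105 and 272 at the detection limit. Without hda6 replicate 1 the total was 8162.

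In sdg2-4, adding ros1-4 lost the STL2P element, with folds of 11.9 and 10.1 in sdg2-4, the EPF2 and XCP2 elements, and elements at AT5G45120 and AIR12. Of the 302 lost elements, 18.5% lay in gene-poor windows against 2.56% of the others (Fisher's exact test, adjusted p = 1.38e-29). Gained elements, 2290 in all, lay at MEE14, SCAMP5, PUB39 and PR5, a pathogenesis-related gene, and at FLC, the flowering repressor (chromosome 5, 3179380 to 3179680, folds of 4.21 and 4.51). MEE14, SCAMP5 and PUB39 also had an element lost in sdg2-4 against Col-0. The PR5 element was listed in 1 Col-0 shoot library and the FLC element in 0. The double lies in another number range than sdg2-4, so preparation cannot be told apart from ros1-4 here. No other pairing gave more than 368. The sdg2-4 ros1-4 comparison gave 756 lost and 623 gained elements with lists of equal length, which turns the larger side, and 120 and 224 at the detection limit. Without sdg2-4 replicate 1 the total was 6994.

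**Figure D4:**
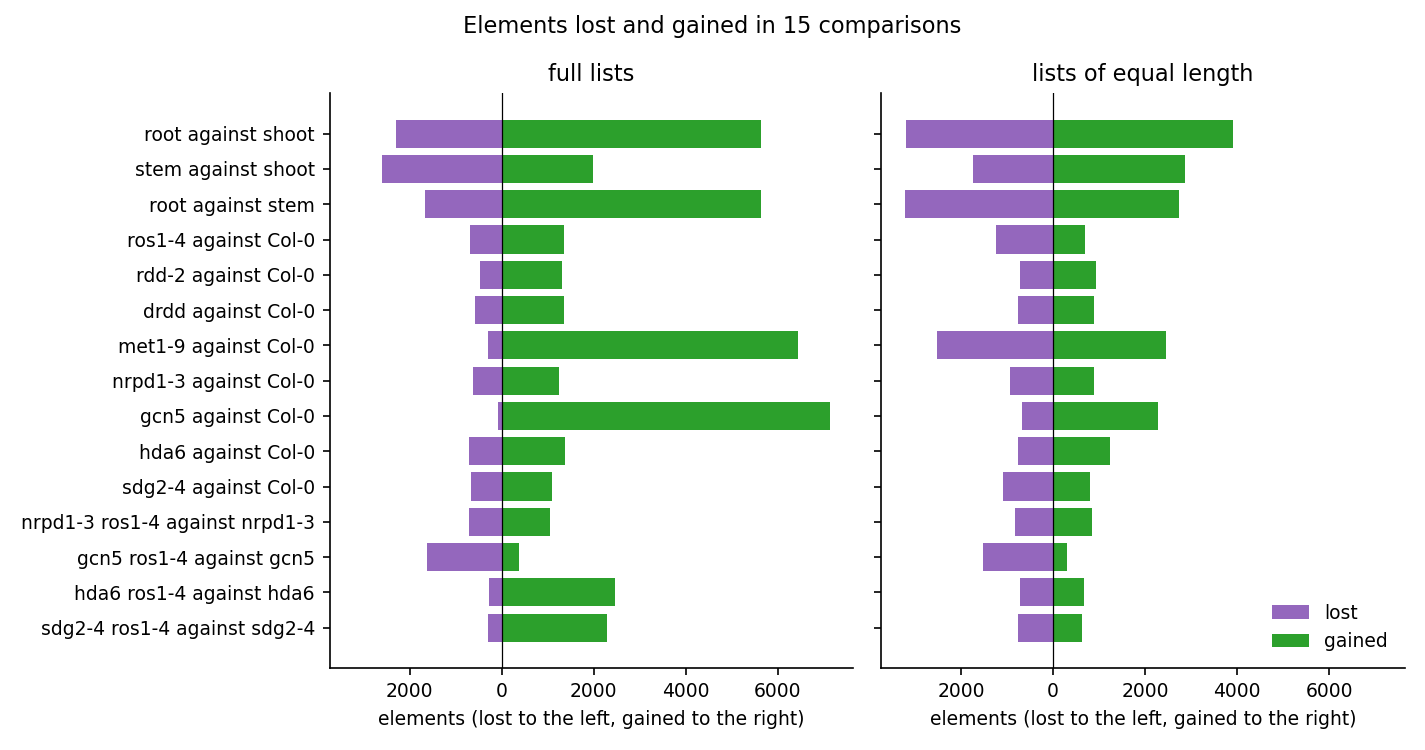
Elements lost (purple, left) and gained (green, right) in the 15 comparisons, from full lists (left panel) and from lists of equal length (right panel). The gained side of met1-9 goes from 6435 to 2457 elements and that of gcn5 from 7124 to 2271.

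The 10 libraries with ros1-4 and the 10 with ROS1, in Col-0, nrpd1-3, gcn5, hda6 and sdg2-4, were compared element by element. An element at AT2G34540 (chromosome 2, 14553503 to 14553803) carried a peak in 10 of 10 ROS1 libraries and 0 of 10 ros1-4 libraries, as did elements at AT4G01350 (chromosome 4, 559571 to 559871) and AT2G24880 (chromosome 2, 10591432 to 10591732) and 3 gene-free sites of chromosome 2 (starts 5840373, 15190039 and 15372972), of which the last 2 lie within 1 Mb of ROS1, like the AT2G34540 element. The median fold was 5.14 at AT2G34540 and 5.11 at AT4G01350. These 2 elements, that at AT2G24880 and that at 5840373 were listed in neither rdd-2 nor drdd. In rdd-2, which also lacks ROS1, the element at 15190039 was listed in 2 libraries and that at 15372972 in 1. Neither was listed in drdd. STL2P and AT2G42005 had 9 and 0 libraries with a peak, and so had ELF4-L3, which was listed in 2 rdd-2 libraries. A gene-free site of chromosome 2 (7239990 to 7240290) also had 9 and 0. It was listed in 2 rdd-2 and 2 drdd libraries, although both genotypes lack ROS1 too. In the other direction AT1G79630 and AT5G44063 had 0 and 9, and PTP1, a protein tyrosine phosphatase gene, had 2 and 10. Among listed genes, XCP2 had 10 and 4, RMG1 10 and 5, and EPF2 6 and 0, while CAL had 4 and 10, BNS 1 and 7, CBP60G 2 and 7 and UBQ5 0 and 5, which were chosen after their values were seen.

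In the exact permutation test within the 5 backgrounds none of 4418 elements passed at an adjusted p under 0.05. The smallest p this test can give, 0.000257, was reached by 6 elements, and the smallest adjusted p was 0.145. At an unadjusted p under 0.05 there were 230 elements with fewer and 949 with more peaks in ros1-4, and at one under 0.001 there were 14 and 2. With lists of equal length there were 391 and 164 at a p under 0.05, so the larger side turns there, and 12 and 0 at one under 0.001, where it does not. The limma model on presence of a peak called 119 lower and 101 higher elements of 22053 at an adjusted p under 0.05. Of 30 elements at listed genes that the exact test could reach, 0 passed adjusted over the list alone and 9 had an unadjusted p under 0.05, and limma gave 0 of 184 adjusted over the list alone and 33 unadjusted. Adjusted over all elements, limma called the XCP2 element (adjusted p = 0.0336). Of the 119 lower elements, 21 lay in gene-poor windows against 4.06% of the others (Fisher's exact test, adjusted p = 1.72e-07), and 39 lay on chromosome 2, or 32.8% against 15.8% (Fisher's exact test, adjusted p = 1.85e-05).

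The elements lost and gained in ros1-4 against Col-0 were followed in the 4 other backgrounds, which were not used to choose them. Of the 687 lost elements, 93.4% carried a peak in gcn5 and 72.3% in gcn5 ros1-4, 66.4% in nrpd1-3 and 58.4% in nrpd1-3 ros1-4, and 64.7% in sdg2-4 and 55.5% in sdg2-4 ros1-4. In hda6 the share was 67.2% without and 70.2% with ros1-4. Relative to all other elements of Col-0 the share changed by −9.01, −20.8, −4.69 and −14.1 percentage points in nrpd1-3, gcn5, hda6 and sdg2-4, lower in 4 of 4 backgrounds and −12.1 on average. The exact permutation test gave p = 0.00154, the smallest its arrangements can give. Gained elements carried peaks more often with ros1-4 by 17.3 percentage points relative to the other elements absent from Col-0. The change was positive in 4 of 4 backgrounds, also at the smallest exact permutation p, 0.00154, and was 10.8 with lists of equal length. The share of gained elements with a peak went from 39.8% to 51.96% with ros1-4 in nrpd1-3 and from 88.6% to 90.7% in gcn5. It went from 41.96% to 81.2% in hda6 and from 47.3% to 84.6% in sdg2-4. In gcn5 the share of the other elements was 50.6% and 44.7% without and 34.7% and 43.9% with ros1-4. Unstable peaks and library depth were not tested for gained elements.

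Within the library number ranges that hold both genotypes (nrpd1-3 and gcn5) the change was −14.9 percentage points for lost and 10.2 for gained elements, each with an exact permutation p of 0.0556, the smallest that 36 arrangements can give. The lost elements no longer passed when they were chosen without ros1-4 replicate 1, at −5.06 percentage points with an exact p of 0.0679, or without ros1-4 replicate 2, at −4.24 with an exact p of 0.0988.

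**Figure D5:**
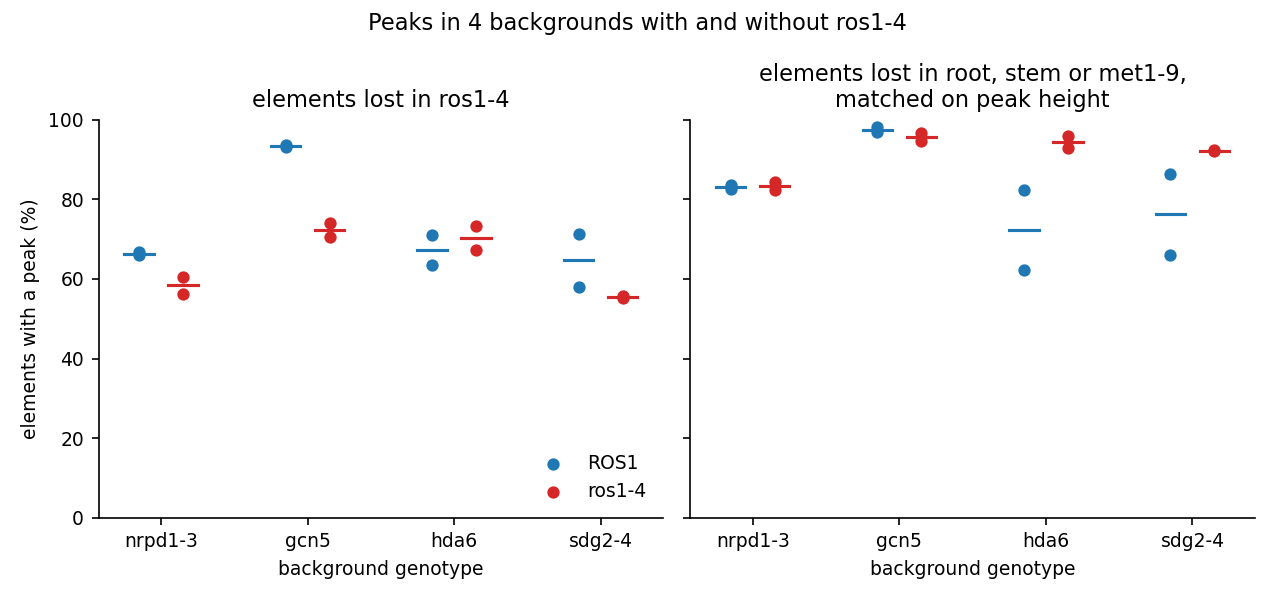
Share of elements with a peak (%) in each library of 4 backgrounds with ROS1 (blue) and ros1-4 (red), for the elements lost in ros1-4 against Col-0 (left) and for elements lost in root, stem or met1-9 and weighted to the same peak height (right); points are libraries and bars are means of 2. In gcn5 the left share goes from 93.4% to 72.3% with ros1-4 and the right one from 97.4% to 95.6%.

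Peak lists as a whole also differed between ROS1 and ros1-4 libraries. A list held 23205 ± 3449 peaks with ROS1 and 26049.8 ± 2350.2 with ros1-4 (SD, n = 10 each; exact permutation p = 0.00797, adjusted p = 0.0159 over 6 values), and both ros1-4 libraries exceeded both others in 3 of 5 backgrounds. Within the number ranges of Col-0, nrpd1-3 and gcn5 the difference was 1338.5 peaks, with an exact permutation p of 0.176. Gene bodies held 7.48% ± 0.332 of elements with ROS1 and 7.88% ± 0.319 with ros1-4, higher in 5 of 5 backgrounds, at the smallest p of the exact test, 0.000257 (adjusted p = 0.00154). Gene-poor windows held 2.77% ± 0.408 and 2.45% ± 0.359, lower in 5 of 5 backgrounds, at the same smallest exact p. Within the number ranges these 2 differences were 0.338 and −0.276 percentage points, each at an exact p of 0.00926, the smallest possible there. Between replicates of most groups the longer list also had the higher gene-body share, as in hda6 (7.76% at 24768 peaks and 7.41% at 17925). In nrpd1-3, hda6 ros1-4 and sdg2-4 ros1-4 the shorter list had the higher share. The shares of classes per library were not compared with lists of equal length, so list length stays open for gene bodies. The median fold of a list was 4.99 ± 0.244 with ROS1 and 5.63 ± 0.211 with ros1-4 (SD, n = 10 each; exact permutation p = 0.000514, unadjusted), with both ros1-4 libraries higher in 4 of 5 backgrounds, and differed by 0.63 within the number ranges (exact permutation p = 0.00926). Covered length was 9727 ± 2387 kb and 10067 ± 1423 kb, an exact permutation p of 0.442.

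The genes removed by the mutations were looked at in every group. ROS1, DME, DML2, MET1 and ATXR3 (SDG2) carried a peak in both libraries of all 15 groups. At ROS1 the highest fold was 8.56 and 9.92 in Col-0 shoot, 17.7 and 12.3 in met1-9 and 5.46 and 6.44 in stem. A further ROS1 element (chromosome 2, 15314594 to 15314894) carried a peak in 5 of 10 ros1-4 libraries and in 1 of 10 ROS1 libraries, with an exact permutation p of 0.0833. NRPD1 was listed in 1 of 2 libraries in Col-0 shoot, gcn5 and met1-9 and in 0 in stem. HAG1 (GCN5) was listed in 0 of 2 sdg2-4 libraries and in 1 of 2 in stem, hda6 and nrpd1-3 ros1-4. HDA6 was listed in 1 of 2 hda6 libraries and in both of every other group. DML3 had no element in any group.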

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

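The tests of unstable peaks against other single mutants, of longer lists, of a different organ and of the longer met1-9 list alone, both tests of the peak number with ros1-4, and the splits for the exact element tests were chosen after the results were seen.

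Relative to the other elements of Col-0, elements lost in ros1-4 carried a peak less often with ros1-4 in 4 other backgrounds, by −12.1 percentage points on average, or −5.06 and −4.24 when they were chosen without ros1-4 replicate 1 or 2. Against 3662 height-matched elements lost in root, stem or met1-9 the difference was −18.0 (exact permutation p = 0.00154, the smallest possible). It was −8.19 in nrpd1-3, the smaller of the 2 backgrounds whose libraries share a number range, and −19.2 in hda6, where both ros1-4 libraries were deeper. These values met the limits set in advance against a change of preparation between ranges and against library depth. They cannot exclude either, because the difference in hda6 came from the matched elements. Those went from 72.3% to 94.4% with ros1-4, and the lost ones from 67.2% to 70.2%. It was set in advance that the value of −18.0 would also exclude unstable peaks. The matched elements were steadier in shoot, with a peak in 83.2% of cases in nrpd1-3 against 66.4%. None of them was lost in ros1-4, so they do not stand for unstable peaks. Against height-matched elements lost in the 3 other single mutants the difference was 3.62 in nrpd1-3 (1.35 and 0.630 without ros1-4 replicate 1 or 2), so those fell as much there, and −12.9 in gcn5 (−10.1 and −8.94), so unstable peaks stay open. The same difference in hda6 and sdg2-4 decides nothing, because these 2 share a number range that their doubles do not.

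Elements gained in met1-9 lay in gene-poor windows. Longer lists are unlikely to be the cause, since with lists of equal length the share was 35.7% against 11.6% of the elements absent from Col-0. A leaf sample in place of shoot could differ by organ. The higher of the shares gained in root and stem was 3.30%, under the 12.1% of all elements absent from Col-0. This test cannot decide, because that reference holds the elements gained in met1-9 (3.55% without them) and leaf itself was not sampled in Col-0. A single deep library met the criterion set in advance, a share under 2 times 12.1% when 1 or the other library is left out, since the share was 16.2% without replicate 2, when the longer and deeper list of replicate 1 alone sets what is gained. That criterion did not single out the deep library, and without it the share was 24.5%, so replicate 1 is unlikely to be the cause.

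Libraries with ros1-4 held more peaks. Depth cannot be excluded as the cause: among backgrounds in which both ros1-4 libraries had more peaks, the lowest difference in background level was −1.35 fragments, in Col-0, where the levels of the 4 libraries overlap. Shorter fragments or sharper peaks may add peaks, since the narrowest peak fell by 18.1 bp with ros1-4 (a difference of −18.1, exact permutation p = 0.0111), so this explanation stays open.

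Splits of the libraries within backgrounds were set beside the real grouping. The real grouping is 1 of the 100 splits. At an adjusted p under 0.05 no split gave an element, the real grouping included, so 100 of 100 splits equal the real count of 0. That count decides nothing, since the smallest adjusted p was 0.145 even where 6 elements reached the smallest p of the exact test. For elements lower at an unadjusted p under 0.001, 1 of 100 splits gave as many as the real 14, the real grouping itself, and the highest of the others was 1. For limma, again only the real grouping, 1 of 100, gave 220, and the highest of the others was 52.

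Covered length with ros1-4 differed by −1978.5 kb in gcn5 against 411 to 1810.3 kb in nrpd1-3, hda6 and sdg2-4; the cause was not tested. Background level differed by −8.53 fragments in gcn5 and by 4.16 in hda6, which was not tested. Elements with a peak differed by −1712.5 in gcn5 against 956 to 5500.5 in the other backgrounds, which was not tested. The pseudogene share differed by −0.028 percentage points in Col-0 and by 0.0156 in sdg2-4, which was not tested. The gene-end share differed by −0.401 percentage points in hda6 and by −0.471 in sdg2-4 against 0.157 to 0.298 in Col-0 and nrpd1-3, which was not tested.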

How the results depend on the processing

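The detection limit, the settings of the overlap among demethylase mutants and those of the gene-poor share were chosen after the results were seen. At the detection limit the changed elements numbered 1482 for root against shoot, 719 for stem against shoot, 1277 for root against stem, 247 for ros1-4, 175 for rdd-2, 348 for drdd, 2073 for met1-9, 282 for nrpd1-3, 752 for gcn5, 330 for hda6 and 150 for sdg2-4. For ros1-4 added to nrpd1-3, gcn5, hda6 and sdg2-4 they numbered 196, 394, 377 and 344. With lists of equal length the totals moved to 2947 in gcn5, 1389 in hda6 ros1-4 and 1379 in sdg2-4 ros1-4. Leaving out each library in turn gave totals of 6368 to 6959 for stem against shoot, 3162 to 4195 for ros1-4, 3018 to 3873 for rdd-2, 3070 to 4206 for drdd, 7768 to 11004 for met1-9, 3234 to 3780 for nrpd1-3, 3506 to 4994 for hda6 and 3183 to 3973 for sdg2-4. For the doubles they were 2966 to 3406 with nrpd1-3, 2511 to 3353 with gcn5, 3678 to 8162 with hda6 and 3441 to 6994 with sdg2-4. Elements lost in ros1-4 differed by −13.6 to −4.24 percentage points in the other backgrounds, and 174 to 397 elements were lost in all 3 demethylase mutants. In the 10 against 10 comparison limma gave 220 elements where the exact test gave 0. The replicate block gave an exact p of 0.0176 for peaks per library and of 0.00781 for the lost and gained elements in other backgrounds, but replicate numbers do not pair libraries. Stratifying by peak height left 35 of 38 class tests on lost elements and added 1. The gene-poor share gained in met1-9 was 41.02% at the detection limit, 35.7% with lists of equal length and 23.3% with the stricter threshold, and 16.2% to 24.5% without each library in turn. For all of these the cause was not tested.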

Other observations

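The tests of distance to ROS1 were chosen after the result was seen, while those of NRPD1 and of chromosome segments were written before.

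QQS carried a peak (chromosome 3, 12348790 to 12349090) in both libraries of met1-9, hda6 and hda6 ros1-4, in 1 of 2 stem libraries and in no other. At RMG1 the element lost in ros1-4 was also absent from drdd and gcn5 ros1-4, was listed in 1 of 2 nrpd1-3 ros1-4 libraries, and was present in both libraries of hda6 ros1-4 and sdg2-4 ros1-4. The weak EPF2 element was listed in 6 of 10 ROS1 libraries and in none of the ros1-4, rdd-2 and drdd groups, with an exact permutation p of 0.0139 that did not pass adjustment. A further EPF2 element (chromosome 1, 12472911 to 12473211) stayed in both libraries of each of these groups.

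Other lists did not pass in the organ comparisons by Fisher's exact test. In root against shoot, AGO4, AGO6 and DRM2 were the 3 of 22 genes of DNA methylation that gained an element (adjusted p = 0.934), and 0 of 4 loci controlled by methylation did. Of leaf and stomatal genes AS2, SPCH and WUS lost an element, 3 of 15 (adjusted p = 0.474), of heat and drought genes COR15A and RD22, 2 of 16 (adjusted p = 0.96), and of housekeeping genes 0 of 17.

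A first hypothesis is that loss of accessibility without demethylases depends on NRPD1, as it would if RNA-directed methylation closed these sites. For 232 elements lost in both rdd-2 and drdd, the share with a peak was higher in nrpd1-3 ros1-4 than in ros1-4 by 34.3 percentage points beyond height-matched elements lost in stem or root. This value does not decide, because the same share was higher than in ros1-4 by 34.9 percentage points in hda6 ros1-4, 23.5 in gcn5 ros1-4 and 16.2 in sdg2-4 ros1-4, where NRPD1 is not removed, and because the matched elements were not chosen for instability in shoot. The hypothesis stays open.

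Another hypothesis is that the lost state is inherited with chromosome segments, so that in a double mutant neighbouring elements would come from the same parent. Whether an element lost in ros1-4 was lost again or kept agreed between next neighbours more often than in shuffles in 4 of 4 backgrounds. Agreement was 66.8% against 63.1% in nrpd1-3, 71.0% against 66.3% in gcn5, 80.7% against 76.1% in hda6 and 68.7% against 52.5% in sdg2-4 (permutation p = 0.0434, 0.001, 0.0003 and 0.0001, the last the smallest possible). In sdg2-4, 51.2% were lost again on chromosome 1 and 19.4% on chromosome 3. Neighbours that share a cause other than descent could give such runs too. No least distance between neighbours was set, so 1 wide peak that covers adjacent elements could also add agreement. Of control elements lost in root, stem or met1-9, 126 were lost in nrpd1-3 and 44 in gcn5, with no excess over shuffles that passed (permutation p = 0.128 and 1), and only 3 in hda6 and 12 in sdg2-4, too few to tell. Control losses were sparser among their elements, 126 of 2775 against 82 of 339 in nrpd1-3, so the other causes stay open.

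Elements lower in ros1-4 were frequent on chromosome 2, which carries ROS1, and sequence from the parent of the mutant allele might have come with it. Linked sequence would lie close to ROS1, but the 39 lower elements lay 4.02 Mb farther away by the median, 7.61 against 3.59 Mb (permutation p = 0.0002), so close linkage is unlikely to be the cause for most of them. Within 1 Mb lay 5 of the 39, or 12.8% against 14.7% of the other elements of chromosome 2 (Fisher's exact test, p = 1). These 5 were listed in none of the 10 ros1-4 libraries, and the elements at 15372972, 15190039 and 14553503, which lie 0.0652, 0.118 and 0.754 Mb from ROS1, were listed in all 10 ROS1 libraries, so linkage stays open for them. In rdd-2, which also lacks ROS1, the element at 15190039 was listed in 2 libraries, that at 15372972 in 1 and that at 14553503 in none.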
